A study of Rattus norvegicus with 4 samples.

How the data were processed

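RNA from the ROE2 line was measured on days 0, 3, 6 and 9 after the move from 33 °C to 37 °C. Per the labels, the medium held 2% serum and 10 ng/ml EGF, RNA integrity numbers were between 9.5 and 10, and cRNA was made from 500 ng of total RNA with a 3' in vitro transcription kit, which labels the part of each transcript near its 3' end. The 4 arrays form 4 groups of 1, taken from the time point in the labels.

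The deposited values are log2 probe set values made by the authors with RMA, per the submitters' processing notes, which corrects background, puts the arrays on a common distribution and summarises the probes of a set. The software, its version and its settings are not given in the sources used here. The log base was inferred from the range, 1.55 to 14.2, and the columns had medians of 5.22, 5.22, 5.24 and 5.24 on days 0, 3, 6 and 9, so they are neither centred per gene nor ratios. No scanner files were used here, so the values were not set against unprocessed intensities. Because RMA gives every array nearly the same distribution, a change in total RNA per cell is not measured, and a shift of most genes in the same direction is largely removed.

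The table has 31099 probe sets, 57 of them controls. The platform annotation gives 1 gene symbol for 20832, several for 436 and none for 9831. Entrez identifiers of 20764 were found in the RefSeq table, and 0 symbols changed. A gene took the probe set with the highest mean over the 4 arrays, which gave 14218 genes, and 8802 of them (61.9%) had a log2 value of 6 or more on at least 1 array. Signal over background was judged from 27 control probe sets for bacterial transcripts outside the hybridisation spike-ins, which read 1.69 to 4.19 on day 0 and up to 4.56 on day 9. Where a named gene was at or below the brightest of these on an array, its fold is given as a bound against it.

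A gene was counted as higher or lower when 2 arrays differed by 1 or more on the log2 scale. With 1 array per group no test was run. For 31 gene lists and 7 lists of markers of other cell types, the median difference from day 0 over members above the floor was set against 10000 random lists of the same size drawn from 20 bins of mean expression, for lists with at least 3 such members. The percentile describes these arrays and is not a test. Early genes were 2-fold or more apart on days 3 and 9 in the same direction, late genes under 1.5-fold on day 3 and 2-fold or more on day 9, and transient genes 2-fold or more on day 3 or 6 and under 1.5-fold on day 9. The groups, the lists, the size rule, the floor, the rule for named genes and most of the alternatives were chosen before the data were examined.

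Named genes were the 12 largest differences in each direction on day 9 among genes with 1 direction on days 3, 6 and 9, the 8 largest in each direction on day 3 and on day 6, the 6 largest in each direction from day 6 to day 9, the 6 largest transient genes in each direction, the 4 members of each list with the largest size on day 9, and a fixed set of keratin, envelope, junction, cycle and reference genes. Genes named outside this rule are Cirbp and Rbm3, chosen before their values were seen, and in the closing part Trib3, Slc7a11, Asns, Ddit3, Hspa5, Hsp90b1, Calr and Mdm2, chosen after their values were seen, as were the fibroblast genes Col1a1, Col1a2, Col3a1, Dcn and Lum, which are members of a fixed list.

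The size rule was tested on simulated data for day 9 against day 0, with 8802 genes at their real means and noise per expression bin from the day 6 and day 9 arrays. Of 50 genes changed by each size, it called 6.00% at 1.5-fold, 48.0% at 2-fold and 100% at 4-fold and 8-fold, and it called 0.267% of unchanged genes. Since noise was taken from 2 arrays that also differ in day, it is an upper estimate for them, though other arrays could be noisier. Probe sets of the same gene parted by a median of 0.38 for day 9 against day 0 and 0.24 for day 9 against day 6. The simulated noise may thus be too small for day 9 against day 0. Of 286 other probe sets of genes called in that comparison, 94.4% went the same way and 48.6% were also 2-fold or more apart. In 100 simulated sets with no change, 13.7 genes were called higher and 12.9 lower on average, at most 25 and 19. Of 100 unchanged lists of 25 genes, 6 fell outside the 2.5th to 97.5th percentile.

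Alternatives were no floor and floors of 5 and 8, the mean over a gene's probe sets, only probe sets whose ID carries no mark of possible cross-hybridisation, centring on the median gene or on the housekeeping list, a further quantile normalization, thresholds of 1.5-fold and 3-fold, overlaps without each day, the mean over list members and unmatched random lists. Centring on the spike-ins and setting values below the floor to the floor were chosen after seeing the data. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.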

Results

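ROE2 is an immortalized epithelial line from the tongue of a fetal transgenic rat that carries a temperature-sensitive SV40 large T antigen, a viral protein that drives proliferation at the permissive temperature and loses function when cells are warmed. Cells were grown at 33 °C for 24 h and then kept at 37 °C for 0, 3, 6 or 9 days, and RNA from each day was hybridised to 1 Affymetrix 3' expression array of the rat genome. The series is about genes of epithelial cell differentiation, and the labels call day 0 the control. There was 1 array per day and so no replicates, which leaves each difference without a replicate check and without a p-value. The day and the array cannot be told apart. The number of arrays limits the precision, and a gene counts as higher or lower below by a fixed rule of size, 2-fold or more between 2 arrays, among the 8802 genes with a log2 value of 6 or more on at least 1 array. "Higher" and "lower" describe these 4 arrays.

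Across those genes the day 6 and day 9 arrays were the most alike, with a Pearson correlation across genes of 0.985, and days 0 and 6 the least alike, at 0.911. Genes are not independent replicates. The median gene lay at -0.05, -0.18 and -0.14 on the log2 scale against day 0 on days 3, 6 and 9. The hybridisation spike-ins, bacterial and phage transcripts added in a fixed amount to every array, were higher than on day 0 on all 3 later arrays, by a median of 0.14, 0.39 and 0.63 over 18 probe sets. Centring the arrays on them would move the median gene to -0.19, -0.57 and -0.77, while centring on the median of all genes would move it to -0.03, -0.02 and -0.03, so list medians are given with the percentile among 10000 random lists matched on expression, which a common shift leaves as it is. The spike-in centring lowers every list median below by the same 0.14, 0.39 and 0.63. The spike-ins themselves did not rise alike. On day 9 the dim bioB transcripts were 0.71 higher and the bright cre transcripts 0.30. Values under this centring therefore show the effect of 1 flat shift, which the spike-ins do not bear out at every intensity. List medians near 0 often moved by over 1.5 times under 1 or more of the alternatives.

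**Figure D1:**
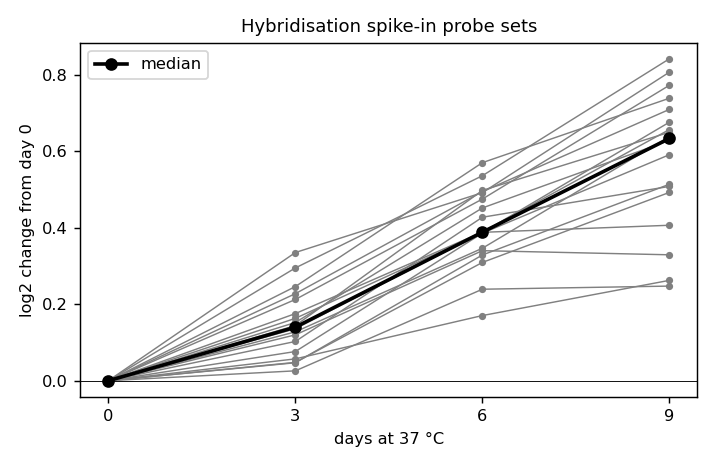
Change from day 0 (vertical axis, log2) of each of the 18 hybridisation spike-in probe sets (grey lines) and their median (black line) by days at 37 °C (horizontal axis), 1 array per day. All 18 lie above day 0 on every later array, and the median reaches 0.63 on day 9.

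On day 3 the genes with the largest differences from day 0 were of several kinds on both sides. Lgals7, which encodes the stratified epithelial lectin galectin-7, was 4.05 higher on the log2 scale, Vsig8 3.70, the selenium transport protein gene Selenop 3.68 and the keratin gene Krt23 3.45. Klk8, a kallikrein protease of the upper epidermis, was at 3.25 on day 0 and 6.88 on day 3, at least 6.45-fold higher. The mast cell protease gene Mcpt8 was at least 7.03-fold higher and the neuronal pentraxin gene Nptx1 at least 11.1-fold. S100g, which encodes the calcium-binding protein calbindin-D9k, was 3.96 higher on day 3 but only 0.80 higher on day 9. Mmp3, the matrix protease stromelysin-1, went from 9.80 to 3.12, at least 43.6-fold lower. The monocyte chemokine gene Ccl2 was 5.76 lower, the TGF-beta feedback gene Pmepa1 4.83, the collagenase gene Mmp13 at least 5.80-fold, the neutrophil chemokine gene Cxcl1 3.06 on the log2 scale, the growth factor gene Csf2 at least 8.04-fold, Ccl7 at least 4.24-fold and Lcp1, which encodes the actin bundler L-plastin, at least 4.61-fold.

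In all, 379 genes were higher and 189 lower on day 3 than on day 0. Of the genes that differed, 33.3% were lower, and 51.5% were lower with arrays centred on the spike-ins. "At least" folds here and below set the bright array against the brightest of 27 bacterial control probe sets on the dim array.

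On day 6 the keratin Krt13, the main suprabasal type I keratin of oral mucosa, was 3.87 higher than on day 0, Krt78 4.17, Krt23 4.02, Vsig8 5.64, Lgals7 5.19 and Selenop 4.11. Klk8 was at least 12.9-fold higher, Kcnj12, a potassium channel gene, at least 13.3-fold and the fetuin gene Fetub at least 13.9-fold. Among the lower genes were Ccl2, at least 75.9-fold, Mmp3, at least 39.1-fold, the interferon-inducible GTPase genes Gbp2, by -4.27, and Gbp4, at least 9.33-fold, Cxcl1, by -4.25, Vim, which encodes the mesenchymal filament protein vimentin, by -4.07, the membrane protein gene Emp3, by -3.56, and Csf3, which encodes the granulocyte growth factor, by -3.53.

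There were 505 genes higher and 711 lower on day 6. The lower genes made up 58.5% of them, against 39.4% with each array centred on its median gene, 46.3% at a threshold of 3-fold and 88.3% with arrays centred on the spike-ins, so which direction held more genes depended on the scaling and on the threshold.

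On day 9, Vsig8 was 59.4-fold higher than on day 0, Lgals7 32.4-fold and Krt13 18.9-fold, and the protease inhibitor gene Slpi was 3.71 higher on the log2 scale. Other genes with the largest differences that kept 1 direction on days 3, 6 and 9 were the transcription factor gene Sox7, from 4.84 to 8.85, C20h6orf15, 3.99 higher, Krt23, 3.67, Selenop, 3.58, Krt78, 3.53, the retinal dehydrogenase gene Aldh1a1, 3.51, and the retinoid-oxidising cytochrome gene Cyp2s1, 3.44. Klk8 was at least 8.55-fold higher. On the lower side were Mmp3, at least 38.0-fold, Ccl2, 21.7-fold, Gbp2, 21.7-fold, Csf3, 13.7-fold, Vim, 12.4-fold, Gbp4, at least 9.05-fold, the cholesterol exporter gene Abcg1, by -3.02, the non-coding Lnc215, by -3.14, the chemokine gene Ccl27, by -2.94, Emp3, by -2.88, Csf2, at least 7.01-fold, and Ccl7, at least 3.70-fold. Some named genes depended on the probe set. With the mean over each gene's probe sets Selenop was at 2.28, Abcg1 at -1.59, Lnc215 at -1.96 and the interferon-inducible Mx2 at 1.20. Of genes named below, another probe set gave less than 2-fold on day 9 for Cldn1 (0.44), Pard3 (0.83), Bnip3l (0.93), Cks1b (-0.44), Rfc5 (-0.77) and Txnrd1 (-0.80), and 2-fold or more for Itgb1 (-1.41), Cdkn1a (1.21) and Tp63 (1.07), and Notch1 was at 0.74, Vldlr at -0.82 and Igfbp3 at -0.049 in another.

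There were 490 genes higher and 550 lower on day 9. The lower genes made up 52.9%, against 41.4% with each array centred on its median gene and 94.4% with arrays centred on the spike-ins. They were also fewer than the higher genes with the mean over each gene's probe sets (48.4%), a floor of 8 (46.7%), a further quantile normalization (46.6%) and a threshold of 3-fold (41.3%).

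**Figure D2:**
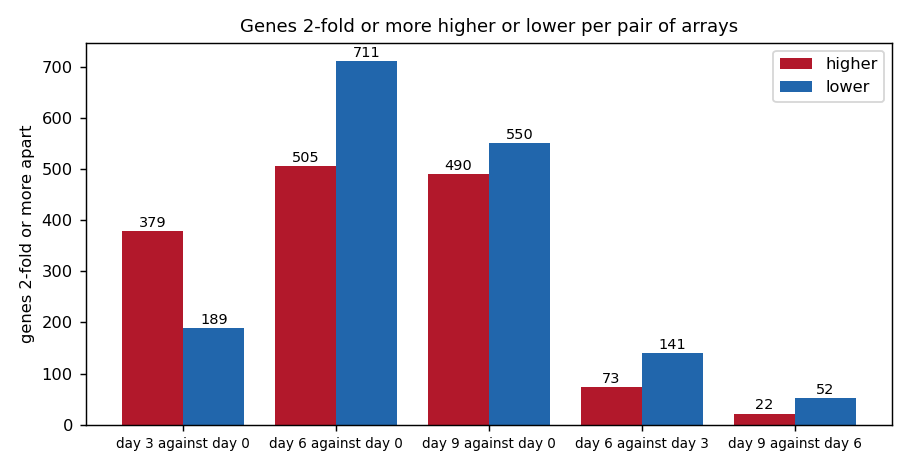
Number of genes (vertical axis) 2-fold or more higher (red bars) or lower (blue bars) in each pair of arrays (horizontal axis), among 8802 genes. Against day 0 the counts lie between 189 and 711, and from day 6 to day 9 they are 22 and 52.

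The suprabasal keratin and cornified envelope lists stood apart from day 3 on. All 5 suprabasal keratin genes above the floor were at least 2-fold higher on each later day, with a list median of 2.55, 3.87 and 3.53, above all 10000 random lists each time. Krt13 went from 9.68 to 13.91, Krt78 from 5.06 to 8.59, Krt10 from 7.20 to 8.78 and Krt1 from 4.32 to 6.80. Krt4, the usual partner of Krt13, was below the floor on all 4 arrays, with 4.16 on day 0 and 4.93 on day 9. The cornified envelope list holds genes of proteins cross-linked into the tough shell of surface cells and other genes of terminal differentiation, among them enzymes. Its median was 0.87, 1.21 and 1.20 on days 3, 6 and 9, also above all random lists. Of its 25 members 9, 15 and 16 were 2-fold or more higher on these days and 0 were lower. On day 9 Loricrin was 2.91 higher, Sprr3 2.68, the cholesterol sulfotransferase gene Sult2b1 2.55, the filaggrin-processing protease gene Asprv1 2.47 and the cross-linking enzyme gene Tgm1 1.31. The list median was 0.57 with arrays centred on the spike-ins. Ivl, the involucrin gene, stayed below the floor. It was at least 1.96-fold and 2.08-fold higher than on day 0 on days 3 and 6. On days 0 and 9, at 3.89 and 4.51, it was not above the brightest bacterial control.

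The lists of transcription factors, lipid enzymes and proteases of the upper epithelial layers stood apart too. Of 16 epithelial differentiation transcription factor genes, 12 were 2-fold or more higher on day 9 and 0 were lower, and the median was 1.32, 1.51 and 1.51, above all random lists. Cebpa, which encodes a factor of postmitotic keratinocytes, was 2.99 higher, Znf750 2.46, Elf5 2.45 and Prdm1, which encodes the repressor BLIMP1, 2.32, while Klf4, already at 12.40 on day 0, was 0.35 higher. Among 10 barrier lipid genes 7 were higher on day 9 and the median was 0.83, 1.27 and 1.26. The sphingomyelinase gene Smpd3 was 2.40 higher, the lipoxygenase gene Aloxe3 and the ceramide desaturase gene Degs2 each 1.91, and the elongase gene Elovl1 1.55. The protease and serpin list had a median of 0.73, 0.90 and 0.64, with 5 of 14 members higher on day 9, among them Klk10 at 2.48, Klk6 at 1.91 and the prostasin gene Prss8 at 2.05. All of these medians lay above every random list. With arrays centred on the spike-ins the day 9 medians of the factor, lipid and protease lists were 0.87, 0.63 and 0.0094, and the protease list was at 0.51 on day 6.

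In the cell junction lists 3 of 11 desmosome and 4 of 17 tight and adherens junction genes were 2-fold or more higher on day 9, and 1 and 0 lower. The desmosome list had a median of 0.28, 0.59 and 0.66, at the 97.9th, 99.7th and 99.9th percentile, against 0.14, 0.20 and 0.029 with arrays centred on the spike-ins and 0.35 on day 9 with values below the floor set to the floor. On day 9 the cadherin genes Dsg1 and Dsc2 were 1.39 and 1.36 higher and the plakoglobin gene Jup 1.13, and Pkp2, a plakophilin of simple epithelia and heart, was lower, by -1.86. The tight and adherens junction list had a median of 0.48, 0.44 and 0.42, above the 99.8th percentile each time, though its day 9 value was -0.21 with arrays centred on the spike-ins. Nectin4 was 1.70 higher on day 9, the claudin gene Cldn1 1.34, the cingulin gene Cgn 1.29 and the polarity gene Pard3 1.06, while the E-cadherin gene Cdh1 differed by 0.19.

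Basal layer genes differed in both directions. Krt5 went from 13.44 on day 0 to 13.16 on day 9. Krt14 was at 14.11 and 14.15, at or near the brightest value of each array, where a change would be hard to see. Krt15, a keratin of basal cells, was 2.68 higher on day 9. The laminin-332 genes Lama3 and Lamb3, which encode the anchor of basal cells to their membrane, were lower, by -1.88 and -1.46, and the integrin gene Itgb1 was at -0.67. The list median was -0.23, -0.25 and -0.39, at the 2.71st, 9.65th and 0.485th percentile, the last of these the 6.81st among unmatched lists, and on day 6 the median was 0.02 with the mean over each gene's probe sets. Tp63, the gene of the basal cell master regulator, differed by 0.41 on day 9. Krt17, the 1 measured wound keratin gene, was 0.91 higher. Of 3 simple epithelial genes above the floor, Krt20 was 2.28 higher, Krt8 was lower, by -1.15, and Epcam was at -0.12, with a list median of 0.52, 0.18 and -0.12 at the 95.9th, 84.5th and 53.5th percentile, and Krt18 and Krt19 were below the floor.

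**Figure D3:**
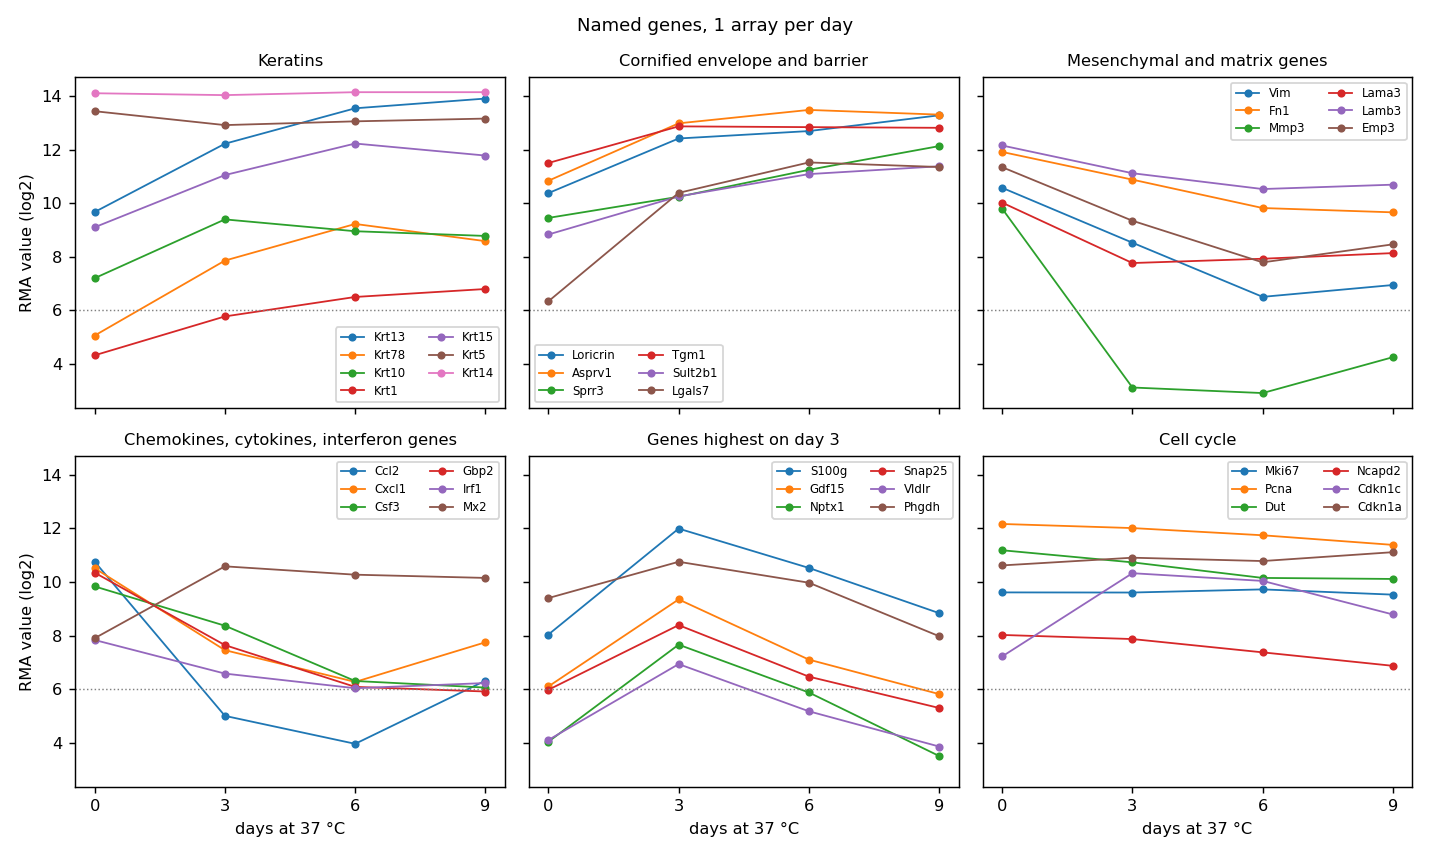
RMA values (vertical axis, log2) of named genes in 6 groups by days at 37 °C (horizontal axis), 1 array per day, with a dotted line at the floor of 6. Krt13 goes from 9.68 to 13.91 and Vim goes from 10.58 to 6.95, while Gdf15 is highest on day 3, at 9.35.

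The epithelial-mesenchymal transition list had a median of -0.88, -0.77 and -0.71, below all or nearly all random lists, and 3 of its 11 members were 2-fold or more lower on day 9, namely Vim, the fibronectin gene Fn1, by -2.26, and S100a4, by -1.18. The cytoskeletal gene Cald1 was at -0.88. With the mean over each gene's probe sets the day 3 and day 6 medians were -0.37 and -0.44, and with no floor the medians were -0.26, -0.19 and -0.29. The YAP, TGF-beta and SMAD list had a median of -0.24, -0.34 and -0.53, at the 1.70th, 5.86th and 0.01st percentile, with 6 of 24 lower on day 9 and 0 higher. Its members include the latent TGF-beta binding gene Ltbp1, by -2.26, the inhibitor of differentiation gene Id2, by -1.94, the matricellular gene Ccn2, by -1.40, and Pmepa1, at -4.83 on day 3 and -1.45 on day 9.

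The inflammatory list held 8 lower genes of 23 on day 3 and 7 on day 9, among them Ccl2, Csf3, Csf2 and Ccl7. Its median of -0.32, -0.29 and -0.16 lay at the 0.58th, 23.6th and 47.2nd percentile. With the mean over each gene's probe sets its day 3 and day 6 medians were -0.20 and -0.04. The interferon list had a median of -0.14, -0.13 and -0.36 at the 21.4th, 67.5th and 9.21st percentile, and its day 9 value was -0.24 with the mean over each gene's probe sets and -0.21 with values below the floor set to the floor. In it Gbp2, the immunoproteasome gene Psmb9, by -2.21, and Irf1, by -1.61, were lower on day 9, and Mx2 was 2.25 higher. The S100 and antimicrobial list went from -0.40 and -0.34 on days 3 and 6 to 0.27 on day 9, at the 0.07th, 4.19th and 96.9th percentile (the last the 97.9th among unmatched lists). It stayed below 0 on all 3 days with arrays centred on the spike-ins, at -0.54, -0.73 and -0.36, and was at -0.12, -0.050 and 0.13 with values below the floor set to the floor. Slpi, the beta-defensin gene Defb4, 2.29 higher, and S100a16, 1.10 higher, stood against S100a4, and S100a9, a calprotectin subunit, was at -1.86 on day 3 and -0.05 on day 9.

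The S phase list shifted from day 3 and the mitosis list from day 6, with few members 2-fold or more apart. The S phase list had a median of -0.33, -0.64 and -0.56 over 47 genes, below all random lists on each day. On day 9 the dUTPase gene Dut was at -1.07, the clamp loader genes Rfc5, Rfc3 and Rfc2 at -1.06, -0.90 and -0.90, and Pcna, the sliding clamp gene, at -0.78. The mitosis list had a median of -0.03 on day 3, at the 58.5th percentile, and then -0.55 and -0.56, below all random lists. The condensin gene Ncapd2 was at -1.15, Cks1b at -1.03, Nuf2 at -0.97 and Kif22 at -0.96 on day 9. On days 3, 6 and 9 the genes 2-fold or more lower numbered 0, 6 and 2 of 47 in the S phase list and 0, 1 and 2 of 49 in the mitosis list, where 2, 1 and 0 were higher, and Mki67, the gene of a common proliferation marker, differed by -0.08. The ribosome biogenesis and MYC list had a median of -0.48, -0.84 and -0.60, below all random lists, with Polr1a at -1.14, Ddx10 at -1.11, Wdr12 at -1.04 and Pes1 at -0.96 on day 9, and Myc itself at -0.30.

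The cyclin-dependent kinase inhibitor and quiescence list had 3 of 17 members 2-fold or more higher and 2 lower on day 9, with a median of 0.39, 0.55 and 0.48 above the 99.9th percentile, but its day 9 value was -0.15 with arrays centred on the spike-ins. Cdkn1c, which encodes p57, was 3.11 higher on day 3 and 1.57 on day 9. The MYC antagonist gene Mxd1 was 2.00 higher on day 9 and Ccng2 1.55, whereas Cdkn2a was lower, by -1.14, and Cdkn1a, which encodes p21, differed by 0.49. The p53 target list did not stand apart. Its median was 0.12, 0.02 and -0.17, at the 96.3rd, 92.0th and 38.9th percentile, with Sesn2 at 0.99, Plk3 at 0.87, Perp at 0.84 and Pidd1 at -1.03 on day 9.

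The unfolded protein response and ATF4 list had a median of 0.54, 0.35 and 0.28, above the 99.9th percentile on each day, and 10, 6 and 2 of its 31 members were 2-fold or more higher. With arrays centred on the spike-ins the day 6 and day 9 medians were -0.040 and -0.35. Phgdh, the entry enzyme gene of serine synthesis, was 1.36 higher on day 3 and at -1.42 on day 9, and the amino acid transporter gene Slc7a5 was 1.08 higher and then at -1.14, while Atf3 was 2.06 and 1.68 higher and the chaperone gene Dnajb9 0.49 and 1.02. The stress cytokine gene Gdf15 went from 6.10 on day 0 to 9.35 on day 3 and 5.81 on day 9, and the lipoprotein receptor gene Vldlr was at least 6.69-fold higher on day 3 and back near the background on day 9. The heat shock list differed little as a whole, with a median of -0.03, 0.04 and 0.08 at the 50.1st, 83.2nd and 86.5th percentile, and 0.20 on day 9 with the mean over each gene's probe sets. Within it Cryab, a small heat shock protein gene, was 2.68 higher on day 9, Hspb1 0.73 and Hspa4l 0.68, and Dnajb4 was lower, by -1.24. Hspa4l had been 2.20 and 1.51 higher on days 3 and 6. Of the 14 members of the heat shock list 3, 3 and 1 were 2-fold or more higher on days 3, 6 and 9, and 0, 1 and 1 lower.

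In the retinoid list 4 of 10 genes were 2-fold or more higher on day 9, and in the NRF2, glutathione and xenobiotic list 3 of 21 were higher and 1 lower. The retinoid list had a median of 0.52, 0.62 and 0.61, above the 99.9th percentile, with a day 9 value of -0.027 when arrays were centred on the spike-ins and medians of 0.10, 0.19 and 0.23 with no floor. The retinol dehydrogenase genes Rdh12 and Dhrs9 were 2.39 and 1.74 higher on day 9, the acyltransferase gene Dgat2 2.18 and the receptor gene Rarg 1.21. The NRF2, glutathione and xenobiotic list had a median of 0.38, 0.24 and 0.24, above the 99.2nd percentile, and -0.15 and -0.39 on days 6 and 9 with the spike-in centring. Its members Aldh3a1 and Aldh1a1, both aldehyde dehydrogenase genes, were 3.39 and 3.51 higher on day 9 and the heme oxygenase gene Hmox1 1.17, while the thioredoxin reductase gene Txnrd1 was lower, by -1.10.

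Signalling lists were mixed. The EGF receptor and ERK list had a median of 0.38, 0.29 and 0.06, at the 99.99th, 99.9th and 93.9th percentile, and its day 6 value was -0.10 with the spike-in centring and its day 3 and day 6 values 0.18 and 0.14 with no floor. Of the 25 members of this list 6, 10 and 7 were 2-fold or more higher on days 3, 6 and 9, and 3, 4 and 5 lower. The largest difference in it on day 9 was that of Mmp3, at least 38.0-fold lower. The immediate early gene Junb and the phosphatase gene Dusp5 were 1.77 and 1.72 higher on day 9 and the feedback gene Spry2 was lower, by -1.87. The Notch list differed little, with a median of 0.09, 0.11 and 0.12 at the 84.4th, 92.5th and 90.7th percentile and 0 of 11 members 2-fold apart on any day, though its day 6 median was 0.31 with the mean over each gene's probe sets. Notch3 was at 0.97, Nrarp at 0.75, Jag1 at -0.62, Rbpj at -0.59, Notch1 at 0.11 and Hes1 at 0.21 on day 9, and probe sets for Rbpj went both ways, from -0.59 to 0.54. The Wnt list had a median of -0.09, 0.24 and 0.17 at the 46.0th, 98.3rd and 95.6th percentile, but it was at -0.33, -0.32 and -0.28 with the mean over each gene's probe sets. With the spike-in centring its day 6 and day 9 values turned to -0.15 and -0.46, and with values below the floor set to the floor to -0.041 and -0.016. Lrp6 and Wnt4 were 1.86 and 1.49 higher on day 9, Lgr5 at least 3.62-fold and Fzd1 was at -0.74.

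In the cholesterol list 2, 4 and 0 of 20 genes were 2-fold or more lower on days 3, 6 and 9 and 0 higher. The list had a median of -0.30, -0.28 and -0.09, at the 0.46th, 11.6th and 54.9th percentile, with Mvd at -1.03 on day 3 and -0.59 on day 9, Stard4 at -0.89 and -0.58, Dhcr7 at -0.59 and -0.70 and Acat2 at -0.80 and -0.51. The oxidative phosphorylation list was at -0.15, -0.22 and -0.22, at the 4.79th, 4.41st and 3.06th percentile, with 0 of 34 members 2-fold apart and Ndufs3 at -0.90, Ndufb3 at -0.65, Sdha at -0.58 and Cox8a at -0.56 on day 9. The hypoxia and glycolysis list was at 0.11, -0.17 and -0.06, at the 95.3rd, 27.6th and 66.2nd percentile, and at 0.12 on day 9 with the mean over each gene's probe sets, with Bnip3l 1.04 higher on day 9, Slc2a1 0.97, Hk2 0.95 and P4ha2 at -0.94. The housekeeping list was at -0.07, -0.16 and -0.15, at the 31.5th, 21.3rd and 25.5th percentile, with Gapdh at -0.03 on day 9 and the transferrin receptor gene Tfrc, lower by -1.41, Gusb at -1.15 and Pgk1 at -0.45.

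**Figure D4:**
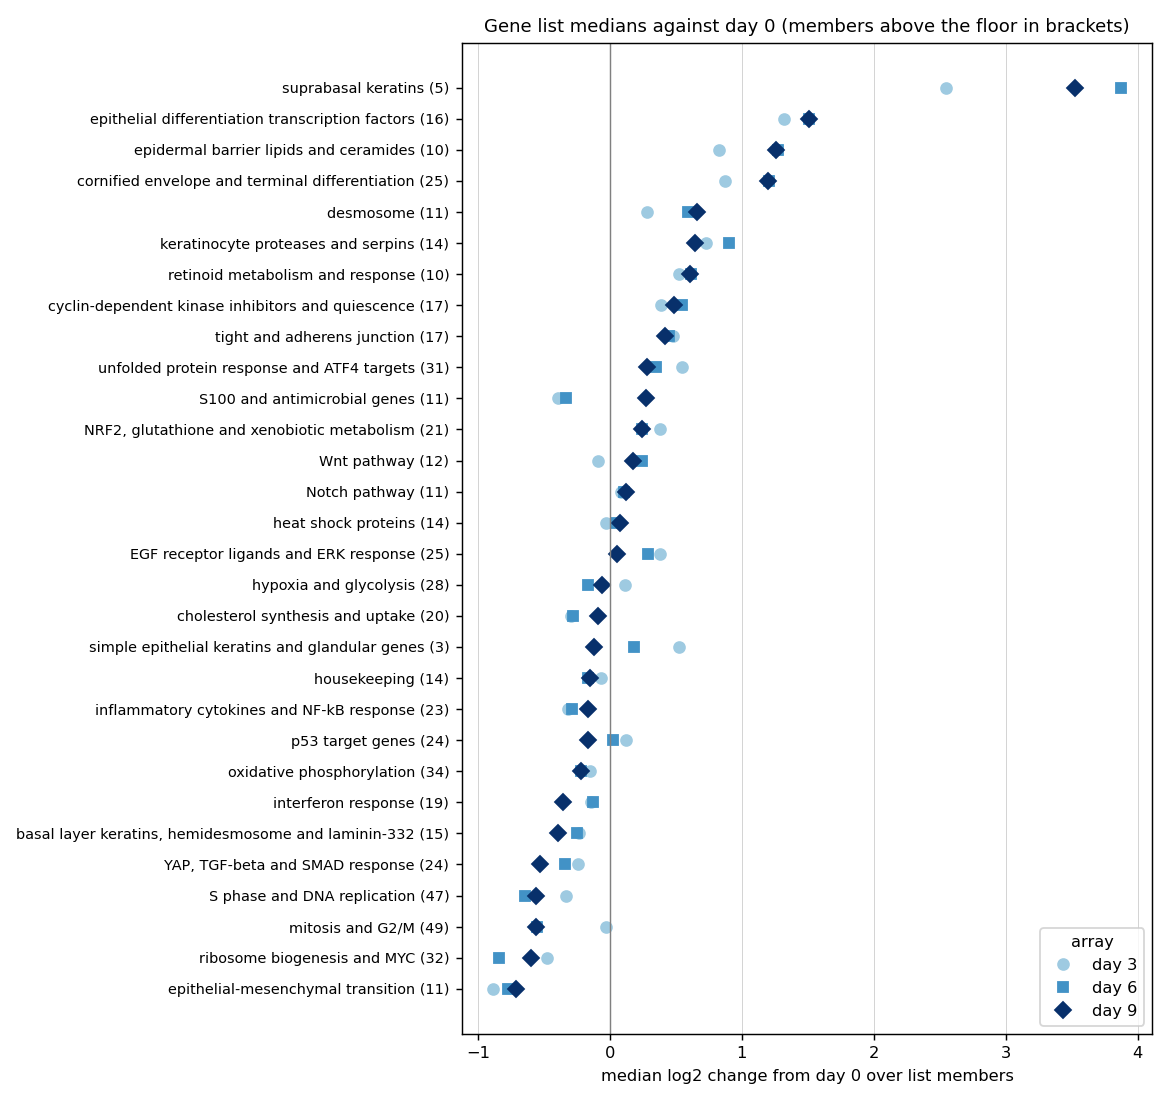
Median log2 change from day 0 (horizontal axis) of each gene list with at least 3 members above the floor (vertical axis, members in brackets) on days 3, 6 and 9 (circles, squares and diamonds). The suprabasal keratins lie highest, at 2.55, 3.87 and 3.53, and the epithelial-mesenchymal transition list lowest on day 9, at -0.71.

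Markers of other cell types were mostly near the background. Of 17 fibroblast markers only Col5a1 and Col5a2 reached the floor, and both were lower on day 9, by -1.27 and at least 3.71-fold, while Col1a1, Col1a2, Col3a1, Dcn and Lum stood at 3.94, 3.22, 2.76, 3.26 and 2.16 on day 0. None of 10 endothelial and none of 8 melanocyte markers reached it. The muscle markers above it were Myh11 and Acta2, at 0.87 and 0.14 on day 9. The leukocyte markers were Cd14, lower by -1.86, Cd68, at 0.86, and Laptm5, at 0.15, with a list median of -0.15, 0.37 and 0.15 at the 39.2nd, 92.5th and 80.7th percentile. The neural markers were Tubb3, 1.21 higher, Snap25, 2.41 higher on day 3 and at -0.68 on day 9, and Mbp, at 0.29, with a list median of 0.21, 0.49 and 0.29 at the 85.4th, 95.6th and 88.7th percentile, and 0.11 and 0.32 on days 3 and 6 with the mean over each gene's probe sets. Of the taste and salivary markers only Kcnn4 reached the floor, and it was lower, by -1.71.

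Between days 3 and 6 the genes that differed were fewer. Csf3 was a further -2.06 lower, Vim -2.02 and Gbp2 -1.56, Gbp4 was at least 1.39-fold lower, and Vsig8 was 1.94 higher, Aldh3a1 1.75 and Pmepa1 2.33. There were 73 genes higher and 141 lower, 65.9% lower, against 45.4% with each array centred on its median gene and 91.4% with the spike-in centring. From day 6 to day 9 only 22 genes were higher and 52 lower, 70.3% lower, against 91.7% with the spike-in centring. Ccl2 was at least 3.49-fold higher on day 9 than on day 6 but still far under day 0, and Mmp13 was at least 2.48-fold higher. Pcdh19, a protocadherin gene, was 1.56 higher on the log2 scale, Cxcl1 1.48, Igfbp3 1.42 and S100a9 1.42. Among the lower genes were Fetub, by -2.03, and Phgdh, by -2.00. Vipr1 was at least 3.26-fold lower, the mast cell protease gene Mcpt10 at least 2.78-fold, Nptx1 at least 2.49-fold and Mcpt8 at least 1.49-fold, all near the background on day 9, so the order of these genes is not measured.

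Genes 2-fold or more apart on all 3 later days numbered 214 higher and 132 lower. Independent lists of those sizes would share 1.21 and 0.954 genes, and simulated arrays with no change shared 0.510 and 0.550 on average and at most 3. Part of the excess may come from the shared day 0 array, which cannot be split. By time course, 218 genes were higher on both day 3 and day 9 and 134 lower, 146 were higher and 231 lower on day 9 after a day 3 value within 1.5-fold, and 98 were higher and 72 lower only for a time. Of the 1582 genes 2-fold or more from day 0 on any day, 683 fell in none of these classes. The transient higher genes with the largest size were Mcpt8, Nptx1, Gdf15, Vldlr, Efhd1 and Vipr1, with Efhd1 2.66 higher on day 3 and 0.50 on day 9. Mcpt8, Nptx1, Vldlr and Vipr1 were at or below the brightest bacterial control on days 0 and 9, so the order of these genes is not measured. The transient lower genes were S100a9, Atxn7l1, at -1.68 on day 3 and -0.07 on day 9, Tmem160, at -1.41 and -0.44, Nefh, at -1.38 on day 6 and -0.41 on day 9, Stard4 and Svip.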

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

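The hybridisation spike-ins, which are used above only to centre the arrays in 1 alternative, were higher on each later array than on day 0. Their median was 0.63 on day 9, with a range of 0.25 to 0.84 over 18 probe sets. The dim bioB transcripts were 0.71 higher and the bright cre transcripts 0.30, so the flat shift of that alternative does not hold at every intensity. The 27 other bacterial control probe sets differed by a median of 0.12.

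Probe sets without a single gene symbol also held differences. Of 2670 with a value at or above the floor, 175 were 2-fold or more higher on day 9 and 254 lower, which is 16.1% of them, against 11.8% of genes with a symbol above the floor. These shares are of unlike units, since a gene counts once by its brightest probe set and these probe sets count singly. The largest differences among the probe sets without a single symbol were 4.87 and -3.76. No name is given to them here.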

How the results depend on the processing

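The counts of genes, list medians and named genes were computed under each alternative, and a count was taken as kept within 1.5 times its main value. Of 222 counts 152 were kept, and of 1047 list medians 835 were kept and 11 called ones turned sign. The mean over list members in place of the median kept 59 of 96 list values and moved 37. Of 1207 values of named genes 1007 moved by less than 1.5-fold. No named gene that was 2-fold or more apart turned sign, while some with smaller values did, such as Klf4, at -0.28 with the spike-in centring. For the centrings this was fixed in advance, since each is 1 shift per array of under 2-fold. By the size of its shift, the spike-in centring moved all 174 values by over 1.5-fold, and the median-gene and housekeeping centrings moved 0 of 174. Fewer genes remain with a floor of 8, by its construction, with 114, 408 and 327 lower on days 3, 6 and 9, 70 lower from day 3 to 6, 12 higher and 29 lower from day 6 to 9, and 76 lower on all days. With each array centred on its median gene 447 were lower on day 6 and 88 from day 3 to 6. At 1.5-fold there were 894 and 883 higher and lower on day 3, 1062 and 2012 on day 6, 1058 and 1728 on day 9, 307 and 805 from day 3 to 6, 234 and 250 from day 6 to 9, and 514 and 600 on all days. At 3-fold these were 125 and 47, 191 and 165, 185 and 130, 16 and 21, 2 and 9, and 72 and 31. Without day 3, 378 were higher and 401 lower on both other days. Centring on the spike-ins, chosen after seeing the data, moved most counts, to 302 lower on day 3, 251 and 1897 on day 6, 174 and 2911 on day 9, 36 and 381 from day 3 to 6, 11 and 121 from day 6 to 9, and 107 and 278 on all days. It left the cornified envelope, mitosis and S phase medians on day 9 at 0.57, -1.20 and -1.19, and turned the sign of the junction list on day 9 (-0.21), the kinase inhibitor list (-0.15), the EGF receptor list on day 6 (-0.10), the ATF4 list on days 6 and 9 (-0.040 and -0.35), the NRF2 list (-0.15 and -0.39), the retinoid list on day 9 (-0.027) and the Wnt list on day 6 (-0.15). On day 6 the Wnt list also turned with the mean over probe sets (-0.32) and with values below the floor set to the floor (-0.041), which gave 13 higher and 31 lower from day 6 to 9. Unless its construction shows it, the cause was not tested. Signal over background limits the dim end, where folds are bounds.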

Other observations

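The tests of probe sets, mesenchymal genes and p53 targets below were chosen after the results were seen, and the test of cold-inducible genes was chosen before.

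Members of the unfolded protein response and ATF4 list differed in their time course. Among the 10 of 31 that were 2-fold or more higher on day 3, Trib3 was 2.13 higher, the cystine transporter gene Slc7a11 2.84, the asparagine synthetase gene Asns 1.29 and Ddit3 1.21, and on day 9 they stood at 0.15, 0.59, -0.25 and 0.43. Of the endoplasmic reticulum chaperone genes in that list, Hspa5 was at -0.08 on day 3 and 0.59 on day 9, Hsp90b1 at -0.13 and 0.36, and Calr at -0.51 and 0.16. These genes were picked from the list after their values were seen, so they stand for no subgroup of the list and no test of a contrast was made.

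Cold-inducible genes were taken as a check of the temperature shift. Cirbp and Rbm3, RNA-binding protein genes that mild cold raises in mammalian cells, would be lower on each later day by a mean of 0.58 or more if the day 0 array carries the state of cells kept at 33 °C. Cirbp was at -1.08, -1.34 and -1.37 and Rbm3 at -0.84, -0.67 and -0.54 on days 3, 6 and 9. The mean nearest to 0 was -0.95, on day 9. All 3 probe sets of Cirbp were lower on day 9, by -1.37 to -2.30. The mean of both genes met the rule on each later day, while Rbm3 alone, at -0.54, fell short on day 9. By design, day 0 differs from the other days by temperature as well as by time in culture and any loss of the large T antigen. This series has no array at 33 °C on a later day to separate these.

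The probe sets of the same gene parted more on some arrays than on others. Over 2700 probe sets that were not their gene's brightest, the median size of the gap between their change and that of the brightest was 0.17 for day 3 against day 0, 0.41 for day 6 and 0.38 for day 9. Dim probe sets reading lower on the later arrays is argued against. The change from day 0 of the dimmer probe sets lay above that of the brightest by a median of 0.22 on day 6 and 0.13 on day 9. Of these probe sets 50.3%, 65.4% and 60.4% lay above their gene's brightest on days 3, 6 and 9. By the same values, the change of the brightest probe set lay below that of the dimmer ones, and gene values here come from the brightest. The bright cre spike-ins also rose less on day 9 than the dim bioB ones, by 0.30 against 0.71. Whether brightness is behind the gap between probe sets was not tested. With the mean over probe sets, which leaves 8163 genes, 557 and 418 were lower on days 6 and 9, against 711 and 550. The higher genes were 476 and 445, against 505 and 490. Labelled RNA of another length may be part of this parting of probe sets and stays open. The 3' minus 5' difference of the beta-actin controls moved by -1.03 on day 6 but 0.10 on day 9. That of the bright GAPDH controls moved by only -0.12 and 0.09. That of hexokinase moved by 0.04 and 0.34, but its 5' probe set was below the brightest bacterial control on all 4 arrays. Only the beta-actin value on day 6 thus goes with this explanation. A change in the 3' ends of transcripts during differentiation was not tested, since probe positions were not used here.

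The lower median of the epithelial-mesenchymal transition list could come from fibroblasts that were lost from the culture, or from the scaling. Against the former, the abundant fibroblast transcripts Col1a1, Col1a2, Col3a1, Dcn and Lum had a median of 3.22 on day 0, within the range of the background, while Vim was at 10.58. The 2 fibroblast markers above the floor, Col5a1 and Col5a2, did go down with the list, at -1.38 and -0.76 on day 3, but fibroblasts would bring the abundant transcripts too. As to the latter, the day 9 median of the epithelial-mesenchymal transition list nearest to 0 under any scaling was -0.61, against -0.71 in the main setting. The scalings shift the values too little, or lower them, to have brought it near 0, so this value decides nothing. The list did lie below all random lists on day 9, a place that a common shift leaves as it is, which argues against a common shift alone. No biological explanation was tested, and temperature, time in culture and large T antigen function were not separated.

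Release of p53 as the large T antigen fails could lower the S phase list and would raise p53 target genes. The target list lay at the 96.3rd percentile on day 3, the 92.0th on day 6 and the 38.9th on day 9, with members in both directions, Gdf15 at 3.25 and Mdm2 at -0.16 on day 3, so these arrays leave the question open. Gdf15 is also a target of ATF4.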
